A study of Homo sapiens with 4 samples.

How the data were processed

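RNA was measured in 4 libraries of DG75, an established human Burkitt's lymphoma line, all from the clone AB7. Per the labels, this clone lacks both native copies of BCL6, a transcriptional repressor of germinal centre B cells, and carries an HA-tagged BCL6 under tetracycline control. The labels give 1 library without doxycycline, called 0 h here, and 1 library each after 16, 48 and 96 h with 1 µg/ml doxycycline. No library without doxycycline was analysed here at a later time, so hours in culture and hours with doxycycline go together. Nothing in the labels repeats a time, and every difference between single times is therefore a value without a replicate check.

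Per the labels' protocols, total RNA was amplified, turned into sense-strand cDNA, fragmented, biotin-labelled, hybridised to an array and stained with streptavidin-phycoerythrin, so the arrays had 1 colour. The authors deposited log2 intensity values in 2 tables of the same libraries. The scale was read from the values, which run from 2.35 to 14.21 in the first table and from 4.46 to 14.11 in the second. The normalization, background correction, summarisation, software and genome build behind either table are not given in the sources used here. Library medians in the first table were 5.31 at 0 h, 5.24 at 16 h, 5.27 at 48 h and 5.28 at 96 h. The first table, with 33297 probe sets, was used for every main value. The second holds 28869 of them with a higher floor, and it supplied gene symbols and an alternative set of values. Deviations of a library from the mean of the 4 libraries correlated at 0.968 to 0.980 between its columns of the 2 tables, across probe sets, which are not independent replicates. The highest such correlation with another library's column was -0.047. Arrays give no read depth, and the number of arrays limits the precision.

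Of the probe sets, 19937 had exactly 1 gene symbol, 2191 had several, 6741 had none and 4428 were only in the first table. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, which was used only for names and for the length of genomic span of each gene, and no coordinates are given because no build is named. The match was by accession for 17017 probe sets, by current symbol for 841 and by older symbol for 836, and 1243 kept the deposited symbol. In all, 3196 symbols were updated. For 621 of the 19088 genes there was more than 1 probe set, and the one with the highest mean over the 4 libraries was taken. Genes with a mean log2 value at or above the 40th percentile, 5.18, were tested, which left 11453.

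Each time was set against 0 h, and 96 h against 16 h, by counting genes with at least a 1.5-fold difference, 0.585 on the log2 scale, without a test. A count over all 3 times took genes with the same sign and at least this size at each. The test set the 3 doxycycline libraries against the single 0 h library, which leaves 2 residual degrees of freedom. It was done with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 11453 genes and a threshold of 0.05. The spread in this test is that between the 3 doxycycline libraries, which holds real change over time, and the 0 h library is assumed to vary alike. Nothing says whether the 4 libraries came from separate cultures, so the p-values measure only the spread between these libraries. Tested on simulated data with 200 of the 11453 genes changed, this fit called 48% of changes of 0.585 and 100% of changes of 1, 1.5 and 2 on the log2 scale, with 14 false calls. Each simulated value was drawn independently with the fitted spread of its gene, as large at 0 h as at the other times. The set changes were equal at all 3 times. The false calls therefore do not show how the fit behaves when times differ or the 0 h library stands apart. To describe what a shared 0 h library gives with such independent spread, 100 sets of unchanged libraries were simulated.

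For 34 gene lists, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. A percentile below 2.5 or above 97.5 is called outside the random lists. It describes these libraries and is not a test of the conditions. Members past the limma threshold were counted over all genes and adjusted over the list alone. The lists, the gene rule, the tests and the rule for named genes were fixed before the data were examined. The rule takes BCL6, the 8 largest differences per direction at each time, the 12 per direction with the largest smallest-of-3 difference, the 10 per direction with the smallest limma p among calls, the 6 largest per direction at 96 h against 16 h, and up to 4 members of each list by mean difference. Small RNA genes, antigen receptor segments and unnamed loci were counted but not named by size. The rule named 146 genes, of which a part is printed. Members of a list that passed the limma threshold are also printed with it, whether or not the rule named them. Flagged genes and cell markers in the closing parts are printed likewise. Other lists and genes outside the rule are said to be so.

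Alternatives were quantile, cyclic loess and median scaling of the deposited values (the last on the median of each library over the tested genes, 7.43, 7.54, 7.50 and 7.46 in the order of the labels), the second table, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, thresholds of 2-fold and 1.3-fold, limma with an intensity trend or robust prior, linear trends in hours or in time rank, and leaving out each doxycycline library. Leaving out a library leaves 1 residual degree of freedom. The prior then had 6.08, 33.96 and 9.27 degrees of freedom without the 16, 48 and 96 h library, against 6.44 in the main fit. Numbers of calls from these fits are therefore not a measure of how well the main calls hold. A lowess correction of each library for genomic span, with a smoother span of 0.3, was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.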

Results

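Gene expression was profiled on 1-colour arrays in clone AB7 of the Burkitt's lymphoma line DG75, in which native BCL6 is disrupted and an HA-tagged BCL6 is under tetracycline control. The purpose stated by the series title is to find BCL6 target genes. There were 4 libraries, 1 without doxycycline (0 h) and 1 each at 16, 48 and 96 h with 1 µg/ml doxycycline. Values are log2 intensities, differences are on the log2 scale, and differences between single times have no replicates and no test. The libraries are named by their labels throughout because BCL6 ran against the labelled order.

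BCL6 was highest in the library labelled 0 h. Its log2 intensity was 11.10 there, 10.58 in the library labelled 16 h, 10.25 in that labelled 48 h and 10.50 in that labelled 96 h. BCL6 was therefore 1.44, 1.80 and 1.52 times lower in the libraries labelled 16, 48 and 96 h. In the limma fit of the 3 doxycycline libraries against the 0 h library, BCL6 differed by -0.66 ± 0.17 (SE), with a Benjamini-Hochberg adjusted p of 0.105, which misses the threshold. The series title calls BCL6 expression inducible in this line, and these values lie the other way. Where the probe set lies relative to the disrupted part of the native gene is not given in the sources used here, so it cannot be said which copy the signal reads. Every direction given from here on is a direction between labelled libraries.

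Set against the library labelled 0 h, 141 genes rose in the doxycycline libraries and 9 fell. CYSLTR1, a cysteinyl leukotriene receptor, rose 10.2-fold (3.35 ± 0.33 SE, limma with Benjamini-Hochberg, adjusted p = 0.00951). TASL, an adaptor of endosomal Toll-like receptors, rose 4.11-fold, BCL2A1, an antiapoptotic member of the BCL2 family, rose 3.95-fold and GPR174, a lysophosphatidylserine receptor, rose 3.28-fold, each with a limma adjusted p (Benjamini-Hochberg) of 0.00951. These folds are on the deposited scale, where CYSLTR1 and BCL2A1 were dim at 0 h, with log2 levels of 4.79 and 4.55. LRRN3, SCN3A, MAML3, ARHGAP15, ANKRD44 and MACC1 rose between 2.52-fold and 2.90-fold with the same limma adjusted p. The kinase SYK (2.62-fold), the adaptor GAB1 (2.83-fold), the lymphoid transcription factors IKZF1 (2.70-fold) and MEF2C (2.30-fold), the stress-induced mTORC1 inhibitor SESN1 (3.10-fold) and the translation inhibitor PDCD4 (3.07-fold) also passed the limma threshold. With the mean of all its probe sets GAB1 was higher by 0.60 in place of 1.503, with an adjusted p of 0.111, and the calls of GAB1 and SYK also ended after the correction for genomic span described below. Genes that fell were HMGCS1, an enzyme of cholesterol synthesis (difference -1.08 ± 0.18 SE), and HSPA5, the main chaperone of the endoplasmic reticulum (-1.04 ± 0.19), with limma adjusted p (Benjamini-Hochberg) of 0.0323 and 0.0454. The others that fell were PMEPA1 (-1.15), LGMN (-0.98), TREX2 (-0.98), SRSF6 (-0.94), OTUD3 (-0.92), TMEM222 (-0.81) and CYP27B1 (-0.79). HMGCS1, HSPA5, TMEM222 and CYP27B1 lost their calls under quantile, loess and median scaling alike, and all of these genes that fell but PMEPA1 lost them after the correction for genomic span and without the expression filter. In all, limma called 141 genes higher and 9 lower at an adjusted p under 0.05 of 11453 tested, and 1171 higher and 585 lower at an unadjusted p under 0.05. The latter were 1140 and 767 with quantile scaling, 1279 and 628 with loess scaling, 1145 and 603 after a correction for genomic span, 1178 and 610 in the second table, and 885 and 1080 with median centring, which shifts all genes of a library alike and moved the median difference of the tested genes to -0.08, -0.08 and -0.05 at the 3 times. Rescaling the libraries reduced the 150 calls to 56 (quantile), 86 (loess) or 49 (median centring), no filter to 54 and a correction for genomic span to 34, while leaving out the library labelled 16, 48 or 96 h gave 226, 261 and 334, of which 28, 21 and 33 were lower. Of the 150 calls, 48 held under all 3 rescalings. No called gene changed sign under any of these settings, and single differences correlated with genomic span across genes, which are not independent replicates (Spearman 0.28 at 16 h, 0.21 at 48 h and 0.11 at 96 h). The fits with a library left out have 1 residual degree of freedom and another prior, so their numbers of calls cannot be compared with the rest.

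**Figure D1:**
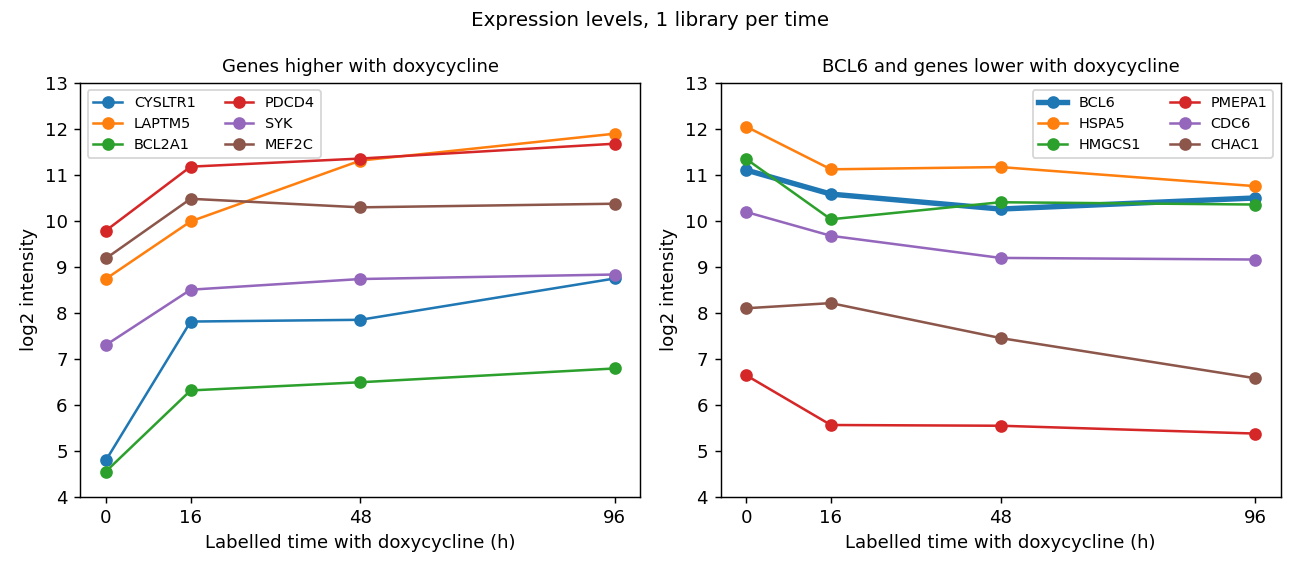
Log2 intensity (vertical axis) against labelled hours with doxycycline (horizontal axis) in the 4 libraries, 1 point per library and no error bars because no time was repeated. CYSLTR1, LAPTM5, BCL2A1, PDCD4, SYK and MEF2C (left) lie lowest in the library labelled 0 h, while BCL6 (right, thick line) goes from 11.10 at 0 h to 10.25 at 48 h, and HSPA5, HMGCS1, PMEPA1, CDC6 and CHAC1 are lower at 96 h than at 0 h.

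At 16 h the largest differences were upward. CYSLTR1 was 8.12-fold higher in the library labelled 16 h than in that labelled 0 h, TASL 4.18-fold, BCL2A1 3.40-fold and IFI44L, an interferon-induced gene, 3.34-fold. ID3, an inhibitor of E proteins, was 3.21-fold higher and GPRIN3 3.10-fold higher. ALDOC, a glycolytic aldolase, was 2.68 times lower at 16 h but only 1.07 times lower at 96 h. HMGCS1 was 2.49 times lower and CYP51A1, another enzyme of cholesterol synthesis, 1.88 times lower. SERPINA9, a serpin of germinal centre B cells, was 1.90 times lower. Counting all genes, 497 were at least 1.5-fold higher and 79 at least 1.5-fold lower, so 86.3% were higher. Centring each library on its median over the tested genes, 7.43 at 0 h and 7.54 at 16 h, made that 57.9% and moved the median difference of the tested genes from 0.02 to -0.08, while quantile and loess scaling gave 81.2% and 85.5%.

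At 48 h more genes were again higher than lower. LAPTM5, a lysosomal membrane protein that limits B cell receptor levels, was 5.95-fold higher in the library labelled 48 h, against 2.38-fold at 16 h. IFI44L was 6.46-fold higher, SAMD9L, an interferon-induced antiviral gene, 3.46-fold higher and TP63, a transcription factor of the p53 family, 3.32-fold higher. The cell cycle gene CDC25A was 2.01 times lower, CDC6, a loader of the replicative helicase, had a log2 level of 9.19 against 10.19 at 0 h, and the histone methyltransferase gene SUV39H1 was 1.99 times lower. NUGGC, a nuclear GTPase of germinal centre B cells, was 1.99 times lower at 48 h and 1.27 times lower at 96 h. PMEPA1 and TREX2 were 2.14 and 2.18 times lower. At least a 1.5-fold difference was seen in 503 genes that were higher and 177 that were lower, 74.0% higher, or 70.5%, 75.9% and 56.4% after quantile, loess and median scaling.

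At 96 h more genes differed by at least 1.5-fold than at 16 or 48 h. IFI44L was 48.2-fold higher in the library labelled 96 h than in that labelled 0 h, CYSLTR1 15.5-fold, IFI27 13.6-fold, LAPTM5 8.92-fold and OAS2, an antiviral oligoadenylate synthetase, 6.36-fold. In the second table the log2 differences of IFI44L and CYSLTR1 were 4.99 and 3.34 in place of 5.59 and 3.96. SP140, a nuclear body protein of immune cells, was 6.16-fold higher. SLC7A11, the cystine transporter, was 3.39 times lower and CTH, which makes cysteine from cystathionine, 2.93 times lower. CHAC1, a glutathione-degrading enzyme induced by ATF4, was 2.87 times lower and CCPG1, a receptor for autophagy of the endoplasmic reticulum, 2.69 times lower. HSPA5 was 2.46 times lower. There were 614 genes at least 1.5-fold higher and 403 at least 1.5-fold lower, 60.4% higher, or 62.0%, 69.3% and 54.4% after quantile, loess and median scaling. At a threshold of 1.3-fold the balance was about even, with 1211 higher and 1231 lower, and at 2-fold 172 were higher and 32 lower.

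Across all 3 times, 264 genes were at least 1.5-fold higher and 22 at least 1.5-fold lower than in the library labelled 0 h, and all 150 limma calls were among them. Among the higher genes, ARHGAP15, a regulator of Rac, was 2.76-fold, 2.56-fold and 2.61-fold higher at 16, 48 and 96 h, and PARP9, an interferon-induced gene, was 2.67-fold, 2.81-fold and 4.42-fold higher. On the low side, DCUN1D2 was 1.62, 1.88 and 2.15 times lower, and PPIF, the mitochondrial cyclophilin, 1.59, 1.65 and 1.99 times lower, neither past the limma threshold. Among the 264 higher genes, 103 stood in the order 96 h above 48 h above 16 h. Unchanged simulated libraries against 1 shared control gave on average 2.59 genes higher and 2.25 lower at all 3 times, and at most 8 and 7. Their noise was independent between genes and as large at 0 h as elsewhere, so a peculiarity of the 0 h library is not covered. With each library in turn set against the other 3, the other 3 were higher and lower for 264 and 22 genes (0 h), 1 and 11 (16 h), 3 and 3 (48 h) and 19 and 25 (96 h). Without the 16 h library, the count over the remaining times was 498 genes in place of 286, with 106 lower and 78.7% higher, and without the 48 h or 96 h library 37 and 34 were lower, and the share of higher genes, 92.3%, was 89.6%, 92.1% and 77.6% after quantile, loess and median scaling.

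The 3 comparisons shared the 0 h library, so their overlap holds a part that comes from that library alone. The 16 h and 48 h comparisons shared 308 higher genes, where independent lists would share 21.8, and 34 lower genes, where they would share 1.2. The 16 h and 96 h comparisons shared 316 higher and 37 lower genes, against 26.6 and 2.8, and the 48 h and 96 h comparisons 392 and 106, against 27.0 and 6.2. Across genes, the differences correlated at 0.78 (16 and 48 h), 0.68 (16 and 96 h) and 0.82 (48 and 96 h), where unchanged simulated libraries gave 0.50 for each pair. The covariances were 0.0703, 0.0733 and 0.0915, which exceed the simulated ones by 0.050, 0.0529 and 0.0712. The single 0 h library cannot be split, and part of the excess may come from it.

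Comparing the libraries labelled 96 h and 16 h, which leaves out the 0 h library, the interferon response list was higher late, with a median of 0.72 and 33 of 33 members higher, and the list of mitochondrial stress and ATF4 targets was lower, with a median of -0.43 and 2 of 30 higher. Both medians kept their direction under each rescaling and after the correction for genomic span, at 0.71 to 0.80 and -0.39 to -0.35. The late fall was not particular to the second list. Medians were -0.42 for G2/M and mitosis (1 of 34 higher) and -0.39 for G1/S and DNA replication (1 of 35). They were -0.22 for oxidative phosphorylation (2 of 38) and -0.21 for housekeeping genes (3 of 25). Antigen presentation genes went the other way, at 0.29 (21 of 22). No random lists were drawn for 96 h against 16 h. IFI44L was higher at 96 h by 3.85, IFI27 by 3.47, LAPTM5 by 1.91, SP140 by 1.79, FCMR, the receptor for IgM, by 1.78 and CCR7, a chemokine receptor for homing to lymph nodes, by 1.70. The lowest were CHAC1 (-1.63), SLC7A11 (-1.55), MAP1A (-1.49), CTH (-1.48), CCPG1 (-1.40) and DNAJC22 (-1.26). At least a 1.5-fold difference was seen in 146 genes that were higher at 96 h and 215 that were lower, so 40.4% were higher. That share depended on the scaling, at 67.8% with median centring, 52.9% with quantile and 53.4% with loess scaling, and 56.6% after the correction for genomic span, so which direction prevails is not settled.

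Interferon response genes made up the list that lay furthest from random lists. Its 33 tested members had a median difference of 0.76 at 16 h, 0.85 at 48 h and 1.37 at 96 h, each at percentile 100. At least a 1.5-fold higher value was found for 18, 26 and 30 members at the 3 times and at least a 1.5-fold lower value for 0, and all 33 were higher in the library labelled 96 h than in that labelled 16 h. Limma with Benjamini-Hochberg called 7 members higher over all genes, IRF1, SAMD9, SAMD9L, PARP9, TAP1, SP110 and PLSCR1, and 26 members when adjusted over the list alone. None of the 7 held under all 3 rescalings, and none after the correction for genomic span. Without the expression filter the medians were 0.43, 0.70 and 1.12, still at percentile 100. Of the members that did not pass over all genes, XAF1 was higher by 1.10, 1.46 and 2.52 and IFI44 by 1.17, 1.73 and 2.53 at the 3 times. Antigen presentation genes had a median of 0.12 at 16 h, inside the random lists, and 0.40 and 0.47 at 48 and 96 h, at percentile 100. Of their 22 tested members, TAP1, the peptide transporter, rose (limma with Benjamini-Hochberg, adjusted p = 0.0468, 0.89 ± 0.17 SE), and 7 when adjusted over the list alone. HLA-DMB, CTSS and B2M were higher at 96 h by 0.69, 0.89 and 0.65. T cell markers had medians of 0.11, 0.21 and 0.21 at the 3 times, inside the random lists, with CD3E higher by 0.67 at 48 h and 0.64 at 96 h, and monocyte markers had medians of -0.12, 0.00 and -0.06 over 2 tested members.

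The list of genes reported as repressed by BCL6 lay higher in the doxycycline libraries, the direction opposite to that of BCL6 itself. Its 33 tested members had medians of 0.27, 0.28 and 0.46 at 16, 48 and 96 h, each at percentile 100, with 9, 8 and 13 members at least 1.5-fold higher. CDKN1B, the cyclin-dependent kinase inhibitor p27, rose 2.10-fold and PDCD4 rose 3.07-fold, the 2 members past the limma threshold over all genes, and adjusted over the list alone 10 were higher and 1, BCL6 itself, lower. The call of CDKN1B ended under quantile and median scaling and after the correction for genomic span. Without the expression filter the medians were 0.14, 0.12 and 0.26, still at percentile 100. GPR183, a receptor that guides activated B cells, was 5.03-fold higher at 96 h and the chemokine gene CCL3 3.42-fold higher, neither past the limma threshold, and in the second table the log2 difference of GPR183 was 1.73 in place of 2.33. The list shares members with other lists, and without BCL6 itself its medians were 0.29, 0.29 and 0.47, with 7 higher and 0 lower over the list alone. Genes of BCL6 corepressors stayed inside the random lists, with medians of 0.11, -0.01 and 0.02, and BCOR was higher by 0.74, 0.61 and 0.73, with 0 limma calls over all genes and 1 when adjusted over the list alone.

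B cell receptor signalling genes lay higher at each time. The 24 tested members had medians of 0.40, 0.45 and 0.70, each at percentile 100, and 15 were at least 1.5-fold higher at 96 h. SYK, GAB1, DAPP1 and the phosphatase PTPN6 rose (limma with Benjamini-Hochberg over all genes), 15 members were higher and 1 lower when adjusted over the list alone, and the adaptor BLNK was 2.61-fold higher at 96 h without passing. DAPP1 and PTPN6 lost their calls under each rescaling, and none of the 4 held after the correction for genomic span, nor GAB1 with the mean of its probe sets. B cell activation and memory genes had medians of 0.21, 0.33 and 0.43, with CD27, a memory B cell marker, and FAS, a death receptor, past the limma threshold among 24 tested and 5 when adjusted over the list alone. NF-kB targets had medians of 0.19, 0.38 and 0.39, with BCL2A1 and IRF1 past the limma threshold among 27 tested and 10 when adjusted over the list alone. Cell adhesion and migration genes had medians of 0.29, 0.23 and 0.31, with ARHGAP15 and TGFBR2, a receptor of TGF-beta, past the limma threshold among 30 tested and 4 when adjusted over the list alone. These lists lay above the random lists at all 3 times. Without the expression filter the medians were 0.09, 0.07 and 0.24 for B cell activation and memory, with 48 h then inside the random lists at percentile 96.82, and 0.17, 0.15 and 0.15 for cell adhesion and migration. FAS and IRF1 lost their calls under each rescaling, CD27 under quantile and median scaling, and TGFBR2 under median scaling. After the correction for genomic span the calls of FAS, IRF1, CD27 and TGFBR2 ended, while those of BCL2A1 and ARHGAP15 held. B cell identity genes lay above them at 48 and 96 h, with medians of 0.13, 0.18 and 0.37, and PAX5, the B lineage factor, rose 1.84-fold and IKZF1 2.70-fold, while 6 of 18 were higher and 1 lower when adjusted over the list alone. The call of PAX5 ended under each rescaling, and without the expression filter the list's medians were 0.17, 0.10 and 0.21, above the random lists at 16 and 96 h.

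**Figure D2:**
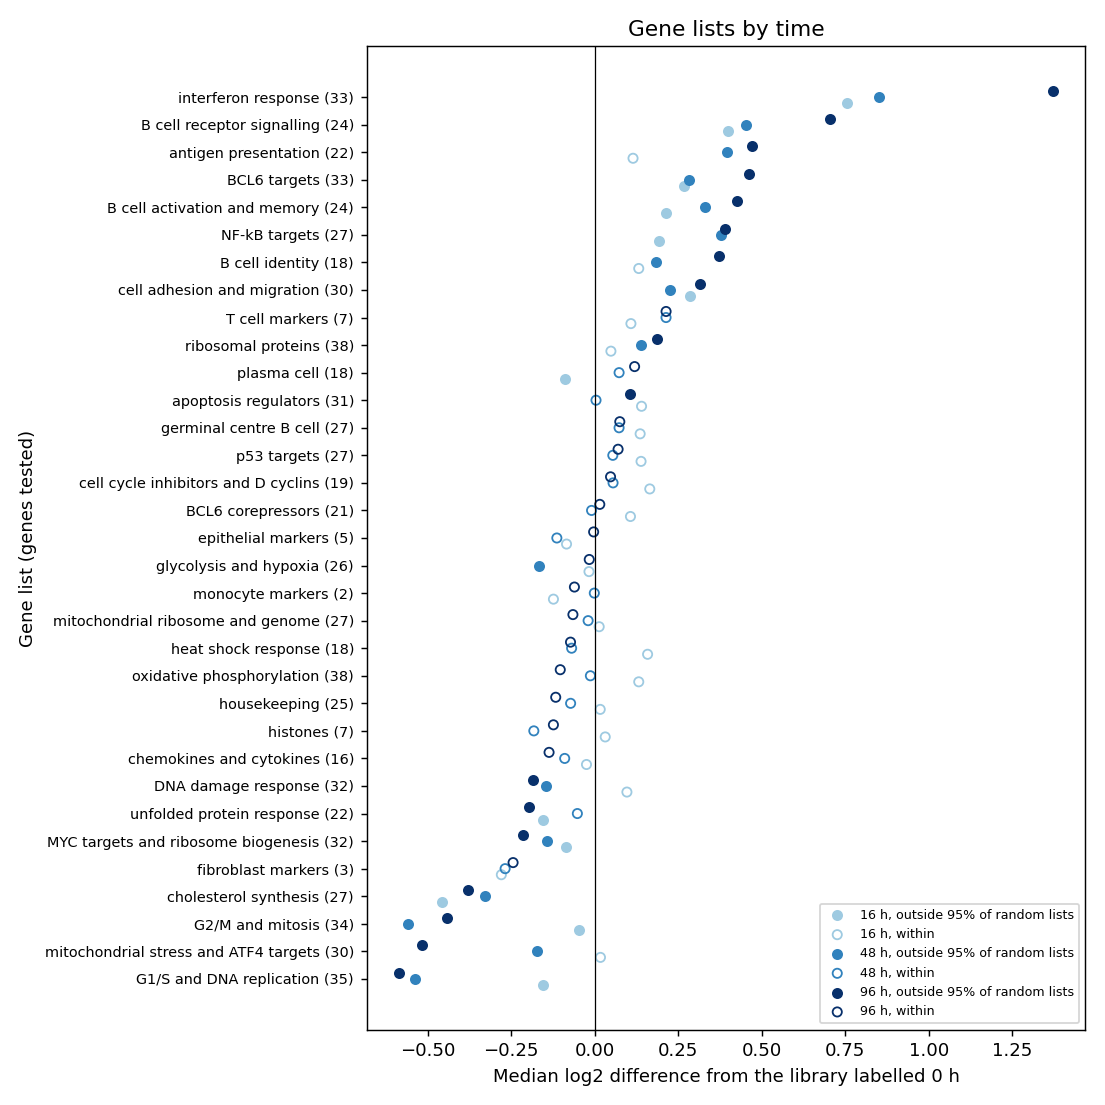
Median log2 difference from the library labelled 0 h (horizontal axis) for 33 gene lists (vertical axis, with the number of genes tested) at the 3 labelled times, 1 point per time. Filled points lie outside 95% of 10000 random lists of matched expression, and the interferon response list reaches 1.37 at 96 h while the G1/S and DNA replication list reaches -0.58.

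Cell cycle genes were lower, mainly in the libraries labelled 48 and 96 h. The 35 G1/S and DNA replication genes had medians of -0.15, -0.54 and -0.58, each at percentile 0.0, and 14 and 17 were at least 1.5-fold lower at 48 and 96 h. None passed the limma threshold over all genes, where the adjusted p of CDC6 was 0.102 with Benjamini-Hochberg, and 6 were lower when adjusted over the list alone. CDC25A was lower by -1.13 and the cell cycle transcription factor E2F8 by -1.10 at 96 h. The 34 G2/M and mitosis genes had medians of -0.05, -0.56 and -0.44, below percentile 2.5 each time, though at percentile 6.09 at 16 h after correction for genomic span. MKI67, the proliferation antigen, was 1.82 times lower at 48 h. Targets of MYC and genes of ribosome biogenesis had medians of -0.09, -0.14 and -0.22 over 32 tested, below percentile 2.5 each time, or at percentile 2.52 at 96 h after that correction, with the transferrin receptor gene TFRC lower by -1.21 at 96 h. Neither of these lists had a limma call over all genes or over the list alone. DNA damage response genes had medians of 0.10, -0.15 and -0.19, below percentile 2.5 at 48 and 96 h, with 0 limma calls over all genes and 1, higher, when adjusted over the list alone. Among cell cycle inhibitors and D cyclins, inside the random lists with medians of 0.17, 0.06 and 0.05, CDKN1B and RB1, the retinoblastoma protein gene, rose 2.10-fold and 2.22-fold, and 5 of 19 when adjusted over the list alone. Both calls ended under quantile and median scaling and after the correction for genomic span.

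Cholesterol synthesis genes were lower from 16 h on. The 27 tested members had medians of -0.46, -0.33 and -0.38, each at percentile 0.0. HMGCS1 fell (limma over all genes), 14 members fell when adjusted over the list alone, and INSIG1, a regulator of sterol synthesis, was lower by -0.60, -0.90 and -0.61. Mitochondrial stress and ATF4 targets lay inside the random lists at 16 h, with a median of 0.02, and below them at 48 and 96 h, with medians of -0.17 and -0.52. Of their 30 tested members, 13 were at least 1.5-fold lower at 96 h, CHAC1 and SLC7A11 among them, while DDIT4, an mTORC1 inhibitor that is also induced by other stresses, rose 2.74-fold (limma with Benjamini-Hochberg, adjusted p = 0.0462, 1.45 ± 0.26 SE), and it was also the 1 call when adjusted over the list alone. That call ended under each rescaling. Unfolded protein response genes had medians of -0.15, -0.05 and -0.20, below percentile 2.5 at 16 and 96 h. HSPA5 fell, 3 of the 22 fell when adjusted over the list alone, and the chaperone genes CALR and MANF were lower by -0.75 and -0.68 at 96 h.

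**Figure D3:**
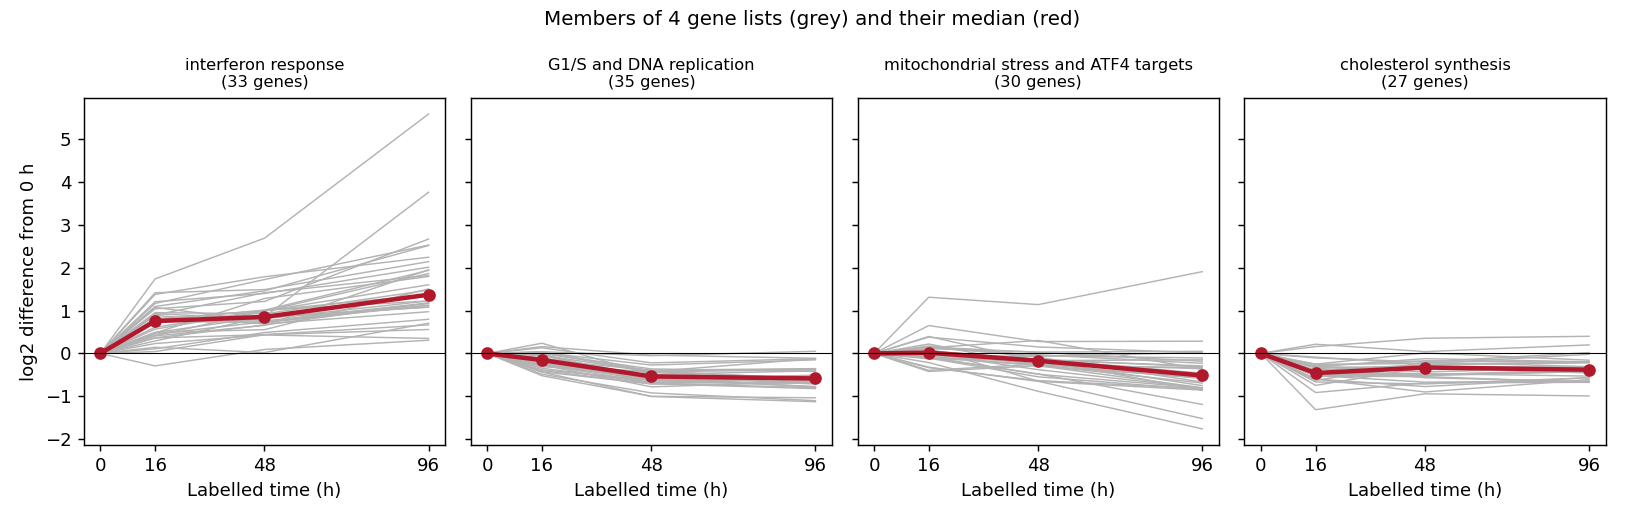
Log2 difference from the library labelled 0 h (vertical axis) against labelled hours (horizontal axis), 1 grey line per gene and the list median in red. All 33 interferon response genes lie higher at 96 h than at 16 h, and the medians at 96 h are 1.37 for interferon response, -0.58 for G1/S and DNA replication, -0.52 for mitochondrial stress and ATF4 targets and -0.38 for cholesterol synthesis.

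Of the remaining lists, some lay outside the random lists at 1 or more times. Ribosomal proteins had medians of 0.05, 0.14 and 0.19, at percentile 100 at 48 and 96 h. Plasma cell genes had a median of -0.09 at 16 h, at percentile 2.04, and 0.07 and 0.12 later, with JCHAIN, the immunoglobulin joining chain, and CD27 past the limma threshold over all genes and 2 when adjusted over the list alone. Apoptosis regulators had medians of 0.14, 0.00 and 0.11, at percentile 98.09 at 96 h, and BCL2A1, BCL2L11, FAS and PDCD4 rose, or 5 of 31 when adjusted over the list alone. Glycolysis and hypoxia genes had medians of -0.02, -0.17 and -0.02, at percentile 0.29 at 48 h, and DDIT4 was the 1 call over all genes and over the list alone. Inside the random lists at each time were germinal centre B cell genes (0.14, 0.07 and 0.08), of which GCSAM, MEF2C and MAML3 rose. Adjusted over the list alone, 6 of these 27 were higher and 1 lower. Likewise inside were p53 targets (0.14, 0.05 and 0.07), of which SESN1, FAS and TP53INP1 rose, with 5 of 27 higher and 3 lower when adjusted over the list alone. Also inside were oxidative phosphorylation (0.13, -0.01 and -0.10), mitochondrial ribosome and genome (0.01, -0.02 and -0.06), heat shock response (0.16, -0.07 and -0.07), chemokines and cytokines (-0.02, -0.09 and -0.14, with IL10RA past the limma threshold and 2 when adjusted over the list alone), histones (0.03, -0.18 and -0.12) and housekeeping genes (0.02, -0.07 and -0.12). Fibroblast markers (-0.28, -0.27 and -0.24, 3 tested) and epithelial markers (-0.08, -0.11 and 0.00, 5 tested) were inside them too, and no erythroid marker passed the expression filter. Under each rescaling JCHAIN, BCL2L11, GCSAM and IL10RA lost their calls, as did TP53INP1 after the correction for genomic span. Per time, 6 lists lay above and 6 below the random lists at 16 h, 9 and 7 at 48 h and 10 and 7 at 96 h, of 33. If all genes varied independently, 1.65 would lie outside. Genes of a list can vary together and lists share members, so more may lie outside between any single libraries.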

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

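Quantile, loess and median scaling were planned; the correction for genomic span and the tests of the exchanged labels, of the BCL6 explanations, of the single 0 h array, of other cells and of mitochondrial stress were chosen after the results were seen, as were the bounds used in this part except those on the gene-span count and on the scaling of the interferon list. PIM2, a survival kinase gene, was lower in the library labelled 16 h (-0.589) and higher in that labelled 96 h (0.734) than in that labelled 0 h, with 1 library each, and the difference between the times was not tested. Probe sets without a single gene symbol, which entered no comparison, were also at least 1.5-fold higher at all 3 times in some cases. Among those above the expression filter these were 22 of 1364 with several symbols, 5 of 1190 with no symbol and 37 of 2639 found only in the first table, against 3, 4 and 28 that were lower. Among the first were probe sets listed for EVI2A and EVI2B (1.85, 1.85 and 2.31), for ATM and NPAT (0.87, 0.93 and 1.25) and for CCL3L1 and related copies (0.87, 1.47 and 1.89, the same values in 3 probe sets), chosen after their values were seen.

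BCL6 was lower in all 3 doxycycline libraries, against the labelled induction. An induced BCL6 that repressed its native locus would also need its other targets to be lower. The lowest percentile of the BCL6 target list without BCL6 was 100 over the 3 times. That list shares members with other lists that were higher, and its members may have risen for other reasons. It therefore cannot decide on the activity of BCL6. The same value of 100 is what a loss of BCL6 with doxycycline would give, with the same limit. A tetracycline arrangement that is switched off by the drug may be a candidate explanation, a hypothesis from these data that the labels do not state. A full loss of the signal was not seen, as BCL6 was lower by only -0.52, -0.85 and -0.61 at 16, 48 and 96 h. It stayed above the median of the tested genes in those libraries, 7.54, 7.50 and 7.46. An exchange of the 0 h label with another was considered on the supposition that BCL6 had been induced after all. That needs the BCL6 target list without BCL6 lower in each of the other 3 libraries than in the one truly untreated. Such an exchange cannot be told apart from the labelled order, since each would rest on single libraries. Against 16 h the list was higher at 96 h by 0.08, at percentile 99.61 but with only 18 of 32 members higher. BCL6 was higher at 16 h (10.58) than at 48 h (10.25) and 96 h (10.50), although that exchange needs it lowest at 16 h. Against 48 h the list was higher at 96 h by 0.25 (26 of 32), although that exchange needs it lower, and level at 16 h (16 of 32). BCL6 was lowest at 48 h, as that exchange needs. Against 96 h the list was lower by 0.25 at 48 h and by 0.47 at 0 h. At 16 h it was lower by 0.08, at percentile 0.39 but with 14 of 32 members higher. BCL6 was lower at 48 h than at 96 h, although that exchange needs it lowest at 96 h. Limma, looked at first, gave 0 calls with any of these 3 libraries set alone against the others, which decides nothing when a treated library may differ from the rest by its hours. A 0 h library from other cells is open too.

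Many more genes were higher than lower in the doxycycline libraries, 141 against 9. For the limma calls the share of higher genes was at least 92.9% under quantile and loess scaling. All of those calls were among the original ones, nearly all of them higher, so the share could hardly fall. It cannot decide on the scaling of the deposited values, which stays open for the limma calls. Median centring shifts all genes of a library alike. For the genes 1.5-fold different at a single time it left 57.9%, 56.4% and 54.4% higher at 16, 48 and 96 h. A fault of that kind therefore stays open as a main part of the excess at single times. Quantile and loess scaling kept at least 85.6% of the excess of these higher genes over an even share, with 62.0% to 85.5% higher. That argues against the faults which those methods remove as the whole cause. For the genes different at all 3 times a trend on genomic span is argued against by 90.1% higher after its correction. For the limma calls that trend stays open, because the correction left 33 higher calls, which meets the figure of under 50 written beforehand for it, while the median size of the difference over the original 150 calls went only from 0.99 (median SE 0.15) to 0.95 (0.15) and 97.1% of the remaining calls were higher; the added requirement that this share also drop was set after seeing the 33. The calls ended with a smaller difference and a prior of 5.15 in place of 6.44 degrees of freedom (median adjusted p of 0.0796 in place of 0.032 for the 150 genes, limma with Benjamini-Hochberg), and rescalings that leave genomic span alone left 44 to 81 higher calls. A peculiarity of the single 0 h array cannot be told apart from the treatment, since it gave 150 calls against the other libraries, the highest for any other library being 0, and 4 ways to single out a library are too few for a share under 0.05.

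Interferon response genes were highest in the library labelled 96 h. RNA of other cells would have to be a large share to raise that list by 1.37. For monocytes it is argued against by the median of 10 markers, -0.051 at 96 h, with LYZ, abundant in these cells, at a log2 level of 3.97 against 4.15 at 0 h and S100A8 at 4.19 against 4.25. For T cells it is argued against by the median of the 7 markers above the expression filter, 0.214 (0.085 over all 10), whose members went both ways, with CD3E at 7.92 against 7.28 but CD7 at 7.53 against 7.73, and by CD3D and CD2, abundant in these cells, at 4.26 against 4.19 and 4.25 against 4.15. A mitochondrial stress response to doxycycline, a drug that can inhibit mitochondrial translation, was examined only through the list of mitochondrial stress and ATF4 targets. A response that raises these genes is argued against by their list, which lay at percentile 0.0 at 96 h. One that acts without them is not covered by the list and stays open. The scaling is argued against by the lowest median of the interferon list over the rescalings, 1.346. Hours in culture, the drug and BCL6 stay open together, as no library without doxycycline was analysed here at 96 h.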

How the results depend on the processing

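Scaling, filter and threshold were varied as planned, and the correction for genomic span was added after seeing the data. The 150 limma calls of any doxycycline against none became 56 with quantile, 86 with cyclic loess and 49 with median scaling, 54 without a filter, 34 after the span correction, 13 as a linear trend in hours and 81 as a trend in time rank, and leaving out a doxycycline library gave 226 to 334. All calls under quantile, loess and median scaling, the second table, no filter and the span correction were among the 150, whereas the trend in hours shared 0 of them and that in time rank 6; a trend asks another question than a common shift, and the cause of the other losses was not tested. The second table gave 110 calls, the 60th percentile filter 121, the mean of probe sets 149, an intensity trend 148 and a robust prior 151. At thresholds of 2-fold and 1.3-fold, which change the counts by construction, there were 95 and 1893 genes at 16 h, 97 and 1964 at 48 h, 204 and 2442 at 96 h, 53 and 804 at all 3 times and 37 and 1603 between 16 h and 96 h. The shares of higher genes were 95.8% and 68.5% at 16 h and 93.8% and 60.5% at 48 h. They were 84.3% and 49.6% at 96 h, 98.1% and 79.5% at all 3 times, and 67.6% and 34.7% for 96 h against 16 h. Leaving out a doxycycline library gave 342 to 498 genes at all remaining times. The other scalings, the second table, both filters and the mean of probe sets kept each total of genes 1.5-fold different within 1.5 times, but not the counts by direction: median centring made 79 lower genes at 16 h 236 and 497 higher 324, 177 lower at 48 h 291, 22 lower at all 3 times 55, and 146 higher and 215 lower at 96 h against 16 h 240 and 114, while the second table made the 79 lower 46 and the stricter filter made them 49 and the 146 higher 86. BCL6 kept its direction in all 15 values under the scalings, the second table and the span correction. Of the 146 named genes, 44 were past the limma threshold and 0 of these changed sign, 1 of the others did (FCN1), and 22 lost their limma call under quantile, 18 under loess and 22 under median scaling, 29 after the span correction and 1 with the mean of probe sets. Of 594 alternative list medians, 100 moved by more than 1 SD of the medians of random lists, 52 of them under median centring and 22 without the filter, and no median outside the random lists changed sign. Without the filter, which changes the members counted, plasma cell genes at 16 h (percentile 13.86), B cell activation and memory (96.82) and B cell identity (97.02) at 48 h, and DNA damage (4.0) and unfolded protein response genes (2.53) at 96 h moved inside the random lists, and antigen presentation, apoptosis regulators and B cell identity at 16 h and germinal centre genes at 48 and 96 h moved above them. Library medians over all probe sets differ by less than 0.1, and the floor of the second table is higher than that of the first. Low genes may be compressed by either, which was not tested. Folds of dim genes such as BCL2A1 at 0 h therefore hold only for the deposited scale, and no background level was used here to bound them. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers.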

Other observations

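The genes named here were chosen after their values were seen, and the list of FOXO targets was tested only after the calls had prompted it. Some further genes past the limma threshold, picked singly and not as a group, were these. BCL11A rose 2.37-fold, IKZF2 2.36-fold, MEIS2 2.33-fold, SATB1 1.89-fold, TCF12 1.79-fold and MYB 1.74-fold, and FOXP1, with a limma adjusted p (Benjamini-Hochberg) of 0.0497, rose 1.94-fold. HIVEP2, a zinc finger regulator, rose 2.63-fold and CAMK4, a calcium-dependent kinase of lymphocytes, rose 2.48-fold. The butyrophilin genes BTN3A1 and BTN3A2, which take part in the recognition of phosphoantigens by gamma delta T cells, rose 2.11-fold and 2.18-fold. Under all 3 rescalings the calls of BCL11A, MEIS2, HIVEP2, CAMK4 and BTN3A1 held, and those of IKZF2, SATB1, TCF12, MYB, FOXP1 and BTN3A2 did not. After the correction for genomic span the call of MEIS2 ended, as did those of IKZF2, SATB1, TCF12, MYB, FOXP1 and BTN3A2.

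A few calls, again picked singly, prompted a hypothesis. SESN1 and SESN3, both sestrins, rose 3.10-fold and 2.68-fold, CDKN1B 2.10-fold, BCL2L11, a proapoptotic member of the BCL2 family, 1.84-fold and DDIT4 2.74-fold, although BCL2L11 and DDIT4 lost their calls under each rescaling and CDKN1B under quantile and median scaling, and all 3 after the correction for genomic span. All of these are known targets of FOXO transcription factors, so higher FOXO activity was taken as a hypothesis, and 20 other FOXO targets whose values had not been looked at were listed before theirs were computed, although the idea itself came from the calls. The 15 of them above the expression filter had medians of 0.34, 0.25 and 0.29 at 16, 48 and 96 h, and the lowest percentile over the 3 times among random lists was 99.61, consistent with the hypothesis. All 20, without the filter, had medians of 0.19, 0.15 and 0.19. The list had 0 limma calls, over all genes or over the list alone, and 2, 1 and 4 members were at least 1.5-fold higher. PIK3IP1, an inhibitor of PI3K, was higher by 1.39 at 96 h and CCNG2, an atypical cyclin, by 0.80, while TXNIP, KLF2 and CITED2 differed by 0.29, -0.17 and -0.12.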
